A study of Mus musculus with 19 samples.

How the data were processed

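The series holds RNA-seq of mouse ESC lines J-34, J-35 and J-37, all labelled male, in several culture media. Per the labels, cells at passage 4 were moved to S/L, 2i/L, a2i/L or PKCi/L for 6 passages, to S/L+PD for 3, or to S/L or 2i/L for 16 passages. A last group was returned from 2i/L to S/L for 3 passages, to passage 23. The media names are used as the labels give them. Per the labels' protocols, cells grew on feeder layers, were passaged with trypsin and were sorted for SSEA1 before RNA extraction. Libraries were made after ribosomal RNA depletion with a strand-marking kit and sequenced as paired ends on an Illumina HiSeq.

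The submitters' processing notes name STAR 2.3.0, Picard 1.100, SAMtools 0.1.18.0, HTSeq 0.6.0 and edgeR 3.8.6, with the builds NCBIM37 and mm9. The deposited table holds linear CPM per gene and library, which the authors rounded to 2 decimals. All 12942 genes listed lie above 1 CPM in at least 3 libraries (the lowest third-highest value is 1.01), a filter read from the values. The columns sum to 292986 to 465897 CPM, less than a whole library, so the authors' totals also hold reads outside the genes listed, and what these were is not stated. No scaling between libraries was visible. From the steps between low CPM values a depth was read for 15 libraries: 33.9 to 45.4 M reads for the 10 libraries of passages 7 and 10, and 50.3 to 85.4 M for 5 of the 9 later ones. Whole reads came back, within 0.1 of a step, for only 1 of 19 columns, so the planned read-based tests with edgeR and DESeq2 were not run.

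Libraries were grouped by medium and passage into 8 groups, S/L, 2i/L, a2i/L, PKCi/L at passage 10 and S/L+PD at passage 7 with 2 libraries each, and S/L and 2i/L at passage 20 and the return at passage 23 with 3 each. All 19 columns were matched to a sample. For the second PKCi/L and S/L+PD libraries the title names line J-37 and the generation label J-35, and the title was used. By the titles, comparisons of PKCi/L and S/L+PD with S/L or 2i/L at passage 10 thus also set J-37 against J-35. Of 13 comparisons 6 were main ones: 2i/L at passages 10 and 20, S/L+PD, a2i/L, PKCi/L and the return, each against S/L. The 7 others set the return against 2i/L, 3 media against 2i/L, and passage 20 against passage 10 in S/L and in 2i/L, and tested the interaction of medium and passage. Every comparison was fixed before the data were examined, as were the gene lists and the rule for named genes.

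Values were tested as log2(CPM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), 1 fit over all 19 libraries with 11 residual degrees of freedom. P values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The planned filter (at least 1 CPM in at least 2 libraries) removed no gene. Named genes are the 5 largest rises and falls of each main and the 3 of each secondary comparison among called genes, up to 4 called genes per list, and a fixed panel of which 15 genes were measured. Some named genes are not reported here. Of 23 fixed lists 22 were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, and the remaining one held sex-linked genes for the label check. Lists were also run with an estimated correlation, and with fry as a self-contained test. Unless TMM scaling is named, that estimate was made without scaling, so it also holds level differences between libraries of a group. Gene sets called in one comparison were read in comparisons that share no library with it, with camera p adjusted over the sets read together.

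Chromosomes were taken by gene symbol from a newer annotation (GENCODE M21), since no table for the build used was at hand. It placed 11604 genes and left 1338 without a chromosome, and only chromosome names and gene order were used. Chromosome levels are medians over genes with a mean of at least 10 CPM.

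Alternatives were TMM scaling (an own implementation), pseudocounts of 0.1 and 1 CPM, no filter, and the ESC line as replicate block (from the title, or from the generation label). Others were each library left out in turn, a 2-fold minimum for the gene sets and lower expression limits for chromosomes. Added after the data were seen were a test of only genes with a mean of at least 5 CPM, one without chromosomes 6 and 8, relative chromosome levels, and 6 further gene lists, of which 5 held at least 3 measured genes. Since line numbers name the same ESC line across groups, pairing was checked. In the groups of 3 libraries residuals of the same line had a median r of 0.101 (-0.145 to 0.339, 5 of 9 pairs above 0.1), against -0.059 for different lines. Over all groups it was 0.036 against -0.006. Residuals cancel within a group by construction, so the values for different lines are no separate baseline. Libraries of one group had a Pearson r of 0.989 to 0.995, and no 2 libraries were identical.

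The scripts were tested on simulated data with 200 changed genes, in which each library was divided by its known scale before the fit. The main fit has no such step. The shares below therefore do not cover shifts of all genes between libraries, or comparisons with many more changed genes. At n = 2 per group, 23.9% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 98.5% of those changed 4-fold were called, with 11 of 12742 unchanged genes called. At n = 3 the shares were 49.3%, 94.0% and 100.0%, with 5 unchanged genes called. A chromosome raised by 0.59 was recovered at 0.58. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for library summaries and figures.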

Results

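The 19 libraries came from male mouse embryonic stem cell (ESC) lines kept in S/L, 2i/L, a2i/L, PKCi/L or S/L+PD medium, and each of 13 comparisons tested 12942 genes. The Y-linked genes Ddx3y (4.27 to 48.4 CPM) and Uty (1.93 to 20.2 CPM) were detected in every library, and Xist, the RNA of the inactive X, stayed at 0.47 to 7.82 CPM. Libraries of passages 20 and 23 stood apart from those of passages 7 and 10: Lars2 read 14870 to 29548 CPM in the 9 later libraries and 56.9 to 3797 CPM in the 10 earlier ones. Lars2 was treated as a feature that resembles ribosomal RNA, so its level is not read as expression of the gene. All genes listed summed to 292986 to 396883 CPM in the later libraries and to 421426 to 465897 CPM in the earlier ones, so most comparisons stay within one of these sets. Values in parentheses are log2 fold changes of CPM + 0.5 with the standard error from limma, a scale that understates changes of genes with low CPM. A gene rose or fell only where it passed the test.

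After 6 passages in 2i/L, ESCs held few transcripts of the ERK feedback genes Spry4 and Dusp6 compared with ESCs kept in S/L to the same passage 10. Spry4, a feedback inhibitor of receptor signalling, fell from 83.9±6.46 to 0.155±0.0636 CPM (mean ± SD, n = 2 libraries each, -7.01±0.22, adjusted p = 1.18e-23). Dusp6, a phosphatase acting on ERK, fell from 64.6±3.88 to 3.2±0.141 CPM (-4.14±0.19, adjusted p = 6.84e-19). The Wnt targets Axin2 (2.66±0.20), Sp5 (5.07±0.23), Cdx1 (3.22±0.20) and Lef1 (3.75±0.25) rose. Of 19 ERK pathway target and feedback genes, 12 fell, 2 rose and 5 did not pass (camera adjusted p = 1.78e-06, adjusted p = 0.19 with an estimated correlation). Dusp4 (-3.17±0.20) and Etv4 (-2.96±0.21) were among those that fell. Of 11 Wnt and beta-catenin targets 10 rose (camera adjusted p = 2.22e-07, adjusted p = 0.0435 with an estimated correlation). Of 9 Hox genes 8 rose (camera adjusted p = 8.34e-06, adjusted p = 0.0435 with an estimated correlation). Among them were Hoxa10 (3.71±0.27) and Hoxd9 (2.27±0.24).

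Among 11 general pluripotency factors 6 fell, 1 rose and 4 did not pass (camera adjusted p = 0.00131, adjusted p = 0.307 with an estimated correlation). Lin28a, an RNA-binding regulator of let-7 (-5.16±0.25), Utf1 (-4.06±0.19) and Pou5f1 (-0.73±0.17, adjusted p = 0.000718) fell, and Nanog (0.97±0.15) rose. Of 15 naive pluripotency factors 5 rose and 1 fell, with no shift of the list (camera adjusted p = 0.259, adjusted p = 0.682 with an estimated correlation). Dppa3 (3.08±0.33), Prdm14 (1.37±0.18), Nr5a2 (1.34±0.18) and Tfcp2l1 (1.1±0.18) were those that rose most, and Klf4 (-0.12±0.14) and Esrrb (-0.09±0.15) did not pass. The de novo DNA methyltransferase genes Dnmt3a (-1.71±0.18) and Dnmt3b (-2.16±0.18) and their cofactor gene Dnmt3l (-4.66±0.20) fell. In all, 6 of 12 genes of the DNA methylation machinery fell (camera adjusted p = 0.0079, adjusted p = 0.489 with an estimated correlation). The maintenance genes Dnmt1 (0.16±0.15, adjusted p = 0.421) and Uhrf1 (0.04±0.16, adjusted p = 0.882) did not pass. Of 27 germline genes with methylated promoters 14 rose and 9 fell (camera adjusted p = 0.13, adjusted p = 0.682 with an estimated correlation). Dazl (3.97±0.23), Tuba3b (3.84±0.30) and Sohlh2 (2.32±0.19) rose and Mael (-3.43±0.24) fell. All 4 measured two-cell stage genes rose, Zscan4c by 1.43±0.25 (camera adjusted p = 0.0134, adjusted p = 0.307 with an estimated correlation).

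Glycolysis genes rose in 14 of 15 cases (camera adjusted p = 5.44e-06, adjusted p = 0.307 with an estimated correlation), with Pfkp (2.47±0.19), Ldha, which makes lactate (2.08±0.19), and the lactate exporter gene Slc16a3 (2.69±0.23). Actin, SRF and YAP targets fell in 9 of 14 cases and rose in 3 (camera adjusted p = 4.88e-05, adjusted p = 0.19 with an estimated correlation). Tagln (-3.70±0.21), Acta2 (-2.60±0.22) and Cnn2 (-2.89±0.19) fell. Of 17 fibroblast markers, 10 rose and 4 fell, with Col3a1 (4.82±0.26) and Col1a1 (2.52±0.21) higher (camera adjusted p = 0.0826, adjusted p = 0.682 with an estimated correlation). Among imprinted genes, 6 of 16 maternally expressed ones fell and 2 rose (camera adjusted p = 0.0175, adjusted p = 0.307 with an estimated correlation), led by the fall of Phlda2 (-3.46±0.23). Of 22 paternally expressed ones 6 rose, with Plagl1 highest (3.75±0.22), and 6 fell, with Peg10 lowest (-2.53±0.16) (camera adjusted p = 0.293, adjusted p = 0.682 with an estimated correlation). Trophoblast markers moved in both directions, 4 higher and 3 lower of 9 (camera adjusted p = 0.926, adjusted p = 0.95 with an estimated correlation). Cdkn1a (2.33±0.19) was one of 5 of 12 p53 targets that rose (camera adjusted p = 0.144, adjusted p = 0.682 with an estimated correlation). Outside these lists the largest rises included Spic (4.96±0.23), S1pr1 (4.84±0.21) and Meis2 (4.72±0.29), and the largest falls Adam23 (-5.23±0.20) and Crmp1 (-4.39±0.23). In limma, 2941 genes rose and 2268 fell, of which 1094 and 823 moved at least 2-fold. Counts adjusted over the list alone were the same except 2 higher and 7 lower for general pluripotency factors and 4 higher and 4 lower for trophoblast markers.

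**Figure D1:**
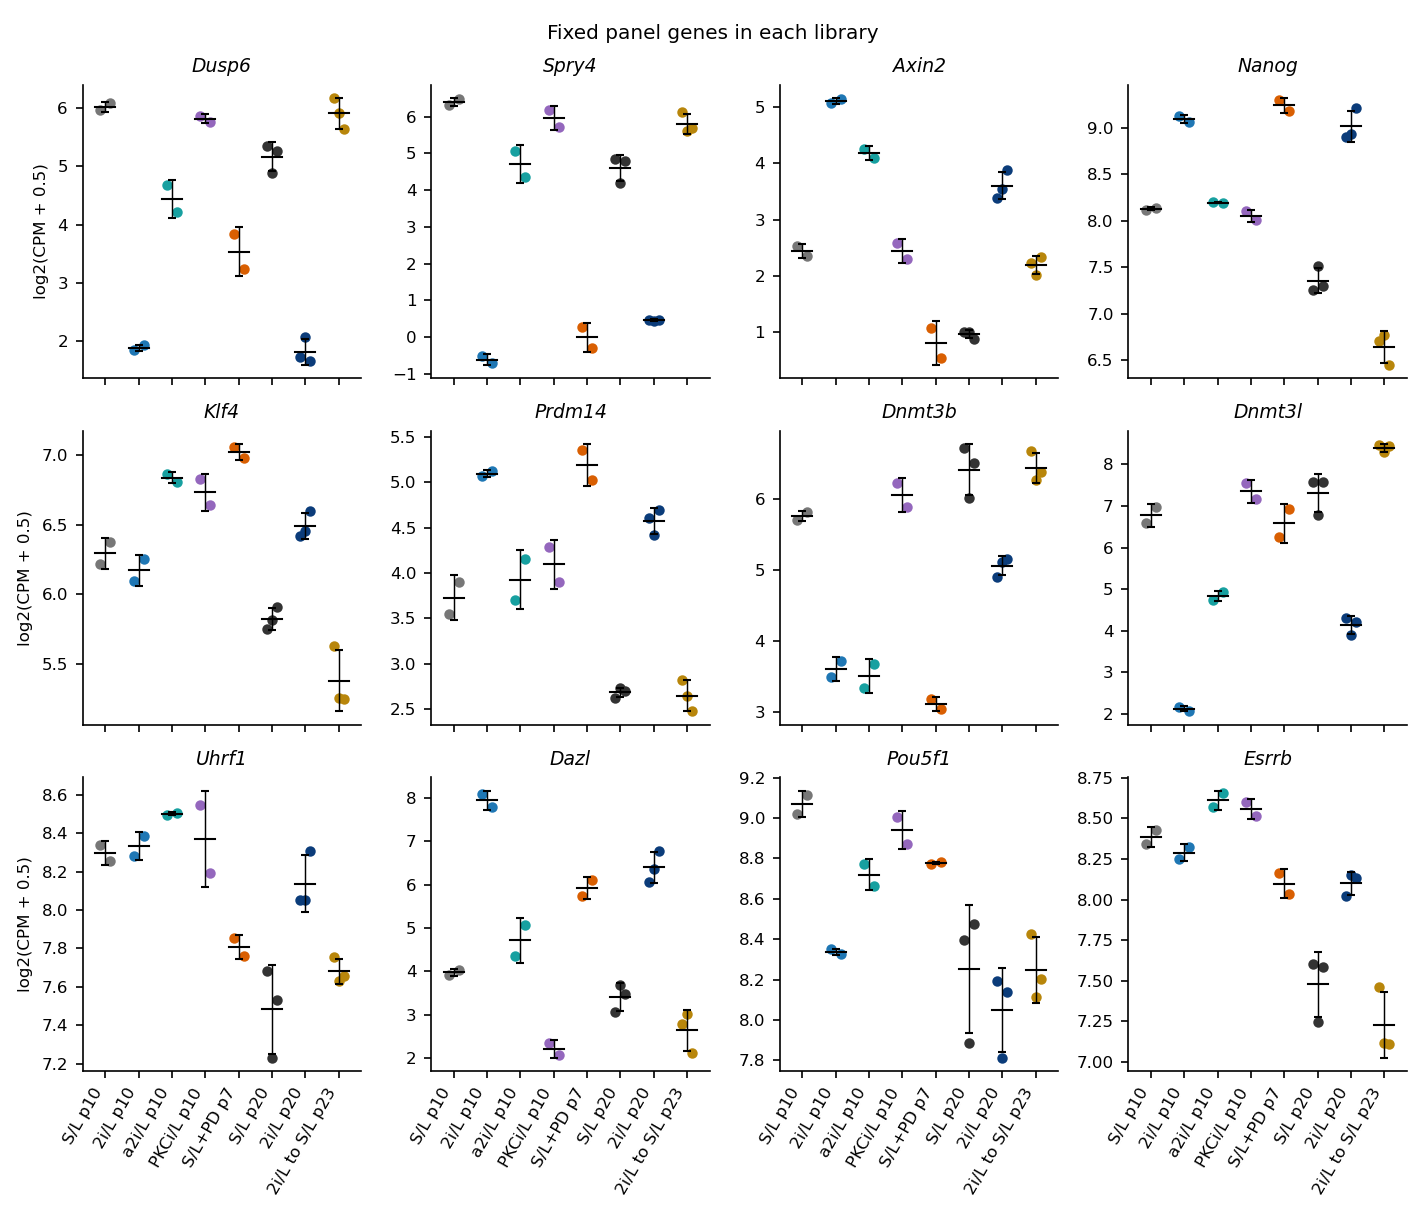
Levels of 12 of the fixed panel genes as log2(CPM + 0.5) in each of the 19 libraries, grouped by medium and passage. Each point is 1 library, and lines give the group mean and SD.

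At passage 20, after 16 passages in 2i/L, cholesterol synthesis genes stood far above S/L, most Wnt targets were higher and several ERK feedback genes were lower. Insig1, a regulator of sterol synthesis, rose from 15.3±3.28 to 117±10.5 CPM (mean ± SD, n = 3 libraries each, 2.92±0.14, adjusted p = 3.3e-19). All 16 cholesterol synthesis genes rose (camera adjusted p = 3.31e-09, adjusted p = 0.21 with an estimated correlation), Sc4mol by 2.85±0.13. These genes were also lower in S/L at passage 20 than in S/L at passage 10, a comparison that crosses the 2 library sets. Spry4 (-4.15±0.18), Dusp6 (-3.35±0.16), Egr1 (-3.60±0.20) and Dusp4 (-2.61±0.16) fell, with 11 of 19 ERK genes lower and 2 higher (camera adjusted p = 2.56e-08, adjusted p = 0.147 with an estimated correlation). Cdx1 (5.33±0.16), Sp5 (3.27±0.19) and Axin2 (2.64±0.16) rose, with 10 of 11 Wnt targets higher (camera adjusted p = 0.000357, adjusted p = 0.147 with an estimated correlation). The remaining one, Lef1, named after its value was seen, fell (-1.01±0.21). All 9 Hox genes rose (camera adjusted p = 4.99e-05, adjusted p = 0.119 with an estimated correlation). Among them were Hoxa10 (3.77±0.22) and Hoxd9 (2.83±0.20).

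Nanog (1.66±0.12), Tfcp2l1 (2.26±0.14), Prdm14 (1.89±0.15), Dppa3 (1.89±0.27), Klf4 (0.66±0.12) and Esrrb (0.62±0.13) rose. Of 15 naive factors 8 rose and 2 fell (camera adjusted p = 0.527, adjusted p = 0.87 with an estimated correlation), and with TMM scaling 8 rose and 6 fell. Lin28a (-5.51±0.20) and Otx2, a factor of the primed state (-3.60±0.20), fell, and Pou5f1 (-0.20±0.14) and Sox2 (-0.23±0.12) did not pass. With TMM scaling Pou5f1 (-0.59, adjusted p = 1.45e-05) and Sox2 (-0.61, adjusted p = 1.16e-07) fell. Without the J-35 S/L library both also fell, Pou5f1 by -0.39 and Sox2 by -0.30, and without the J-37 2i/L library Sox2 fell by -0.31. General factors fell in 5 of 11 cases and rose in 3 (camera adjusted p = 0.00064, adjusted p = 0.225 with an estimated correlation). Formative and primed markers split evenly, 3 higher and 3 lower of 8 (camera adjusted p = 0.0322, adjusted p = 0.439 with an estimated correlation), and with TMM scaling 1 rose and 4 fell. Dnmt3l (-3.18±0.17), Dnmt3b (-1.35±0.15) and Dnmt3a (-0.50±0.15) fell, and Dnmt1 (0.54±0.12) and Uhrf1 (0.65±0.13) rose. With TMM scaling Dnmt1 lost its call (0.15, adjusted p = 0.0628). The methylation machinery held 6 higher and 4 lower of 12 (camera adjusted p = 0.446, adjusted p = 0.87 with an estimated correlation). Germline genes fell in 11 of 27 cases and rose in 7 (camera adjusted p = 0.00123, adjusted p = 0.439 with an estimated correlation). Mael fell (-3.10±0.20) and Dazl rose (2.99±0.19). Imprinted genes moved in both directions. H19 (3.33±0.23), Igf2 (2.45±0.22) and Plagl1 (4.23±0.18) rose, and Grb10 (-2.29±0.23) and Peg10 (-2.09±0.13) fell. The maternally expressed list held 4 higher and 7 lower of 16 (camera adjusted p = 0.00467, adjusted p = 0.225 with an estimated correlation). The paternally expressed list held 11 higher and 9 lower of 22 (camera adjusted p = 0.143, adjusted p = 0.574 with an estimated correlation). With TMM scaling the paternal split turned to 7 higher and 10 lower.

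Fibroblast markers rose in 11 of 17 cases and fell in 4 (camera adjusted p = 0.143, adjusted p = 0.74 with an estimated correlation). The collagen genes Col3a1 (4.77±0.21) and Col1a1 (3.75±0.17) and Postn (3.88±0.23) rose, whereas the contractile gene Tagln (-2.12±0.17) fell. Actin, SRF and YAP targets fell in 10 of 14 cases and rose in 2 (camera adjusted p = 7.82e-08, adjusted p = 0.119 with an estimated correlation), Thbs1 by -2.13±0.20. Glycolysis genes rose in 9 of 15 cases and fell in 1, but with TMM scaling in 6 and 5 (camera adjusted p = 0.79, adjusted p = 0.97 with an estimated correlation). Of 12 p53 targets 7 rose, Cdkn1a by 2.35±0.15, and 3 fell, a split that TMM scaling turned to 3 higher and 5 lower (camera adjusted p = 0.93, adjusted p = 0.97 with an estimated correlation). The remaining large moves were rises of Dmgdh (4.47±0.22) and Cd3g (4.25±0.19) and falls of Enpp3 (-4.13±0.18), Hist1h2aa (-3.75±0.23) and Pla2g7 (-3.68±0.18). In limma 6469 genes rose and 1592 fell (80.3% higher), around a median shift of 0.33 for all genes. With TMM scaling, which removes that shift, 4075 rose and 4268 fell (48.8% higher), so gene values and counts given without TMM scaling hold the shift. Counts adjusted over the list alone were the same except 4 higher and 4 lower for formative and primed pluripotency markers and 7 higher and 12 lower for germline genes with methylated promoters. The same adjustment gave 12 higher and 4 lower for fibroblast (feeder) markers and 2 higher and 11 lower for actin, SRF and YAP target genes.

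The effect of 2i/L differed between passage 20 and passage 10 for 4792 genes in limma's interaction test. The effect was higher at passage 20 for 3873 and lower for 919, around a median shift of 0.29, against 2536 and 2567 with TMM scaling. Cholesterol synthesis genes had a higher effect at passage 20 in 14 of 16 cases (camera adjusted p = 3.16e-08, adjusted p = 0.608 with an estimated correlation). Among them were Sc4mol (2.48±0.21) and Mvd (2.45±0.21). Glycolysis genes had a lower effect in 10 of 15 cases (camera adjusted p = 1.31e-07, adjusted p = 0.608 with an estimated correlation). Pgk1 (-1.59±0.23) and Ldha (-1.41±0.24) were 2 of them. Germline genes had a lower effect in 12 of 27 cases (camera adjusted p = 9.73e-08, adjusted p = 0.608 with an estimated correlation), with Sohlh2 (-2.87±0.25) and Tuba3b (-2.80±0.39). The basement membrane genes Col4a1 (3.48±0.27) and Col4a2 (2.70±0.29) were among 7 of 13 primitive endoderm markers with a higher effect (camera adjusted p = 0.0105, adjusted p = 0.608 with an estimated correlation). The largest differences were those of Inhbb (4.55±0.29), Adam23 (4.17±0.26) and Cntn2 (4.16±0.31) upward and of Hist1h2aa (-4.78±0.37), Lef1 (-4.76±0.33) and Igfbp4 (-4.22±0.28) downward. Groups had n = 2 libraries at passage 10 and n = 3 at passage 20. Counts adjusted over the list alone were the same except 3 higher and 14 lower for germline genes with methylated promoters.

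In S/L+PD, at passage 7, collagen and other fibroblast genes were among the largest rises compared with S/L at passage 10. In that comparison the medium and 3 passages differ together, and by the titles also the line of the second library (J-37 against J-35). The collagen gene Col3a1 rose from 0.61±0.127 to 218±90.0 CPM (mean ± SD, n = 2 libraries each, 7.56±0.26, adjusted p = 2.64e-23). Of 17 fibroblast markers 16 rose and none fell (camera adjusted p = 3.35e-28, adjusted p = 0.0165 with an estimated correlation). The collagen crosslinker gene Lox (7.64±0.32), Col5a2 (7.45±0.23), Col1a1 (6.65±0.21) and Col1a2 (6.64±0.28) belonged to that list. Col12a1 (7.87±0.25) and A2m (6.70±0.18) rose as strongly outside it. Together with these markers, actin, SRF and YAP targets rose in 11 of 14 cases (camera adjusted p = 5.23e-14, adjusted p = 0.0165 with an estimated correlation). Thbs1 (6.36±0.24), Acta2 (4.82±0.22) and Ctgf (3.5±0.18) belonged to these. TGF-beta and BMP targets rose in 6 of 12 cases (camera adjusted p = 0.0139, adjusted p = 0.411 with an estimated correlation). ERK pathway genes fell in 13 of 19 cases and rose in 3 (camera adjusted p = 2.79e-05, adjusted p = 0.411 with an estimated correlation). Spry4 (-6.40±0.22), Etv4 (-4.52±0.21) and Dusp6 (-2.49±0.19) fell, and Fos, an immediate early gene, rose (5.49±0.27).

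Wnt targets did not move as a list, with 3 higher and 3 lower of 11 (camera adjusted p = 0.719, adjusted p = 0.874 with an estimated correlation). Axin2 (-1.64±0.20) and Cdx1 (-2.70±0.20) fell and Lef1 (2.08±0.25) rose. Of 15 naive factors 8 rose, including Prdm14 (1.46±0.18), Klf2 (1.61±0.21) and Klf4 (0.72±0.14), and 2 fell, Gbx2 (-3.41±0.24) and Nr0b1 (-2.49±0.20) (camera adjusted p = 0.302, adjusted p = 0.816 with an estimated correlation). Nanog (1.11±0.15) and Otx2 (2.83±0.25) rose, and Pou5f1 (-0.29±0.17) and Sox2 (0.26±0.15) did not pass. Sox2 rose with TMM scaling (0.32, adjusted p = 0.00343). Of 9 LIF and STAT3 targets 5 rose and none fell (camera adjusted p = 0.0421, adjusted p = 0.425 with an estimated correlation). DNA methylation genes fell in 9 of 12 cases (camera adjusted p = 0.000767, adjusted p = 0.411 with an estimated correlation). Dnmt3a (-2.70±0.18), Dnmt3b (-2.65±0.18) and the imprint protector gene Zfp57 (-1.17±0.16) fell, while Dnmt3l did not pass (-0.20±0.20, adjusted p = 0.485). Cholesterol synthesis genes fell in 11 of 16 cases (camera adjusted p = 1.31e-05, adjusted p = 0.411 with an estimated correlation). Dhcr7 (-1.36±0.18) and Lss (-1.23±0.16) were among them. Glycolysis genes rose in 11 of 15 cases (camera adjusted p = 3.21e-06, adjusted p = 0.411 with an estimated correlation), with Slc16a3 (2.75±0.23) and Ldha (2.09±0.19). Dazl (1.95±0.23), Tuba3a (2.01±0.19) and the imprinted H19 (2.5±0.28) rose, and Ntn1 (-4.16±0.25), Inhbb (-3.89±0.23) and Trh (-3.87±0.32) were among the largest falls. Germline genes fell in 14 of 27 cases and rose in 8 (camera adjusted p = 0.375, adjusted p = 0.865 with an estimated correlation). In limma 2120 genes rose and 2498 fell, 898 and 614 of them at least 2-fold. Without the J-37 S/L+PD library 1601 genes fell. The counts for these lists adjusted over the list alone were the same except 3 higher and 14 lower for ERK pathway target and feedback genes, 4 higher and 3 lower for Wnt and beta-catenin target genes and 9 higher and 15 lower for germline genes with methylated promoters. The same adjustment gave 6 higher and 3 lower for TGF-beta and BMP target genes and 12 higher and 1 lower for glycolysis genes.

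**Figure D2:**
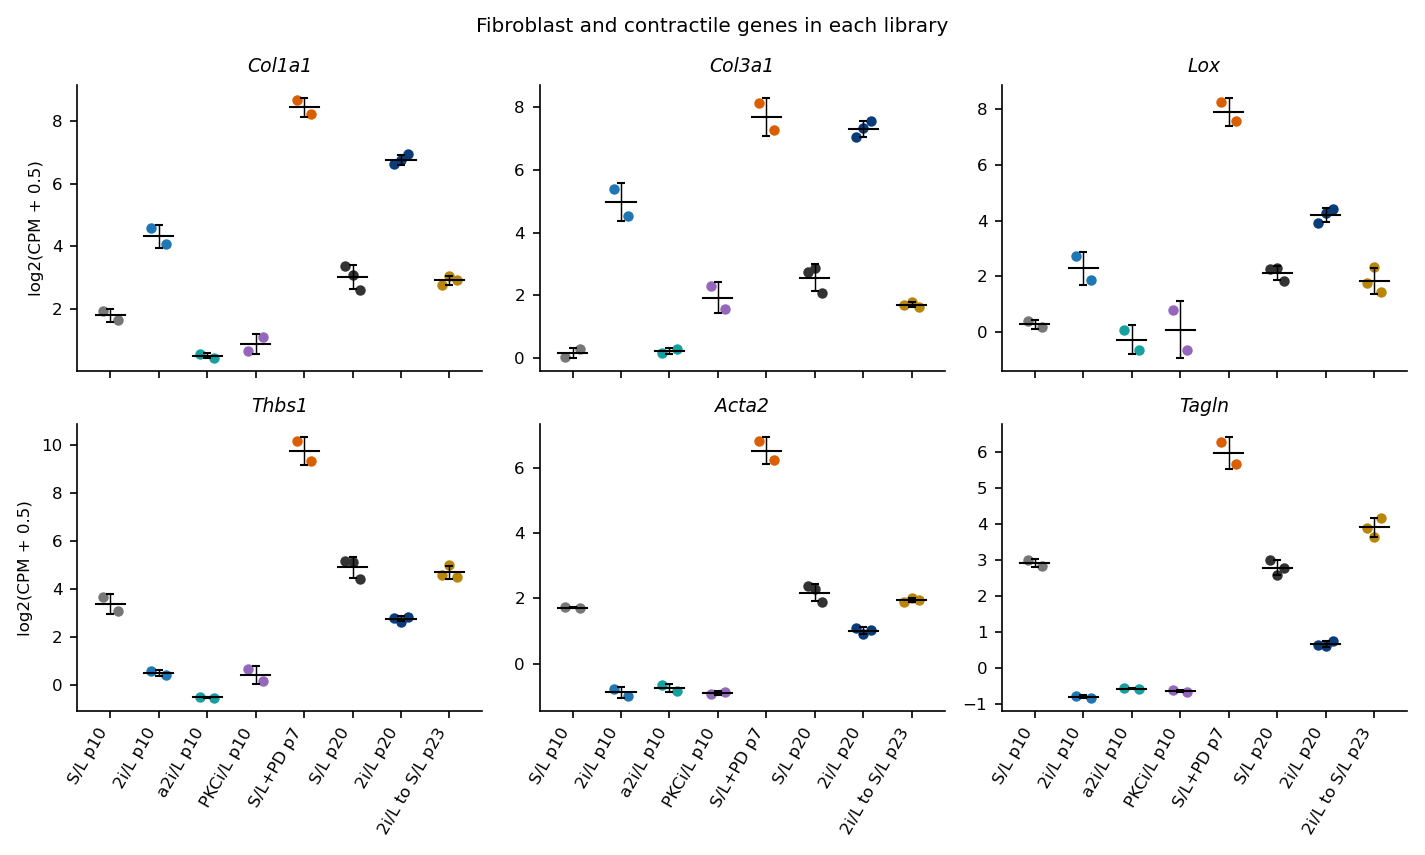
Levels of fibroblast and contractile genes as log2(CPM + 0.5), by medium and passage. Points are single libraries, with the mean and SD of each group.

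In a2i/L at passage 10, every glycolysis gene rose compared with S/L, and actin, SRF and YAP targets fell. Ldha rose from 203±52.1 to 1145±137 CPM (mean ± SD, n = 2 libraries each, 2.51±0.19, adjusted p = 5.67e-13). Slc16a3 (3.27±0.23) and Pgk1 (2.05±0.18) were among the 15 glycolysis genes, which all rose (camera adjusted p = 7.88e-21, adjusted p = 0.0667 with an estimated correlation). Thbs1 (-3.88±0.24), Tagln (-3.48±0.21) and Acta2 (-2.47±0.22) were among 11 of 14 actin, SRF and YAP targets that fell (camera adjusted p = 7.03e-10, adjusted p = 0.0548 with an estimated correlation). The Nodal targets Lefty1 (-3.98±0.34) and Lefty2 (-2.67±0.25) and the BMP target Id1 (-2.46±0.26) fell, as did 8 of 12 TGF-beta and BMP targets (camera adjusted p = 1.96e-05, adjusted p = 0.126 with an estimated correlation). Cdx1 (3.38±0.20), Lef1 (2.61±0.25) and Axin2 (1.73±0.20) rose, with 5 of 11 Wnt targets higher and 1 lower (camera adjusted p = 1.96e-05, adjusted p = 0.0667 with an estimated correlation).

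ERK pathway genes fell in 11 of 19 cases and rose in 4 (camera adjusted p = 0.00761, adjusted p = 0.419 with an estimated correlation). Etv4 (-1.90±0.21), Spry4 (-1.69±0.22), Dusp4 (-1.63±0.20) and Dusp6 (-1.58±0.19) fell and Ier3 rose (2.47±0.24). Dnmt3b (-2.26±0.18), Dnmt3l (-1.95±0.20), Zfp57 (-1.59±0.16) and Dnmt3a (-1.09±0.18) fell, 7 of 12 in their list (camera adjusted p = 0.000355, adjusted p = 0.387 with an estimated correlation). The paternally expressed Peg3 (-1.99±0.16), Peg10 (-1.97±0.16) and Mest (-1.97±0.20) were among 9 of 22 that fell, against 4 that rose (camera adjusted p = 0.0797, adjusted p = 0.42 with an estimated correlation). Primitive endoderm markers fell in 7 of 13 cases (camera adjusted p = 0.000727, adjusted p = 0.262 with an estimated correlation), with Col4a1 (-2.61±0.21) and Lamb1 (-1.77±0.17). Fibroblast markers fell in 7 of 17 (camera adjusted p = 0.0173, adjusted p = 0.462 with an estimated correlation). Of 3 mesendoderm markers measured 2 rose, Eomes by 2.13±0.20 (camera adjusted p = 0.00101, adjusted p = 0.0548 with an estimated correlation). Nr0b1 (-1.82±0.20) fell, Tfcp2l1 (0.99±0.18), Klf4 (0.54±0.14) and Stra8 (2.22±0.23) rose, and Nanog (0.07±0.15) and Esrrb (0.23±0.15) did not pass, though Esrrb rose with TMM scaling (0.30, adjusted p = 0.0108). Without the J-34 S/L library Klf4 lost its call (0.46, adjusted p = 0.0731). The largest rises were A2m (5.43±0.18), Igfbp4 (4.82±0.22), Pygl (4.41±0.23), Ndrg1 (4.37±0.21) and Ndufa4l2 (4.02±0.24), and Lrp2 (-3.58±0.24) was among the largest falls.

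In limma 3617 genes passed in a2i/L against S/L, 1381 higher and 2236 lower, or 2270 and 2488 with TMM scaling. The number of called genes was lower by a similar amount whichever library was left out, which leaves n = 1 in its group. It was 2304 (902 higher, 1402 lower) without the J-34 and 2389 (982 and 1407) without the J-35 S/L library. Without the J-35 a2i/L library it was 2281 (862 and 1419), and without the J-34 one 2537 (1069 and 1468). Called genes adjusted over the list alone were the same except 4 higher and 13 lower for ERK pathway target and feedback genes, 6 higher and 1 lower for Wnt and beta-catenin target genes and 0 higher and 8 lower for DNA methylation machinery. The same adjustment gave 0 higher and 8 lower for primitive endoderm markers, 3 higher and 0 lower for mesendoderm and primitive streak markers and 1 higher and 9 lower for TGF-beta and BMP target genes.

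In PKCi/L at passage 10, germline and primitive endoderm genes fell compared with S/L, and genes of glycolysis and of early neural development rose. By the titles the second library of the 2 groups also differs in line (J-37 against J-35). Fkbp6, a gene of the male germ line, fell from 6.68±1.08 to 0.515±0.0778 CPM (mean ± SD, n = 2 libraries each, -2.82±0.28, adjusted p = 3.85e-10). Of 27 germline genes 21 fell and none rose (camera adjusted p = 3.44e-11, adjusted p = 0.119 with an estimated correlation). Among them were Mov10l1 (-2.35±0.22), Dpep3 (-2.24±0.24) and Dazl (-1.76±0.23). Of 13 primitive endoderm markers 11 fell (camera adjusted p = 2e-08, adjusted p = 0.0604 with an estimated correlation). Among them were the laminin gene Lamb1 (-2.85±0.17) and Sparc (-1.45±0.15). The neural progenitor genes Pax6 (2.03±0.26), Nes (1.71±0.22) and Sox11 (1.33±0.24) rose, 4 of 5 neuroectoderm markers in all (camera adjusted p = 1.94e-05, adjusted p = 0.0604 with an estimated correlation). Zic2 (3.43±0.19), Zic5 (1.84±0.18) and Otx2 (1.08±0.25) were among 4 of 8 formative and primed markers that rose (camera adjusted p = 1.31e-05, adjusted p = 0.119 with an estimated correlation). Otx2 did not pass without the J-34 S/L library (0.75, adjusted p = 0.069).

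ERK pathway genes as a list did not shift, with 4 lower and 2 higher of 19 (camera adjusted p = 0.948, adjusted p = 0.977 with an estimated correlation). Dusp6 (-0.20±0.19) and Spry4 (-0.45±0.22) did not pass, Etv4 fell (-2.80±0.21) and Ier3 rose (1.77±0.24). Among Wnt targets Lef1 rose (4.91±0.25), Axin2 did not pass (0.00±0.20) and 7 of 11 stayed uncalled (camera adjusted p = 0.291, adjusted p = 0.766 with an estimated correlation). Glycolysis genes rose in 14 of 15 cases (camera adjusted p = 4.54e-25, adjusted p = 0.0604 with an estimated correlation). Among them were Slc16a3 (2.75±0.23), Pgk1 (2.25±0.18) and Ldha (2.21±0.19). Actin, SRF and YAP targets fell in 10 of 14 cases (camera adjusted p = 2e-08, adjusted p = 0.0604 with an estimated correlation). Tagln (-3.53±0.21), Cyr61 (-3.39±0.18) and Ctgf (-2.3±0.18) fell and Vim rose (2.34±0.18). Of 15 naive factors 5 rose, with Klf2 (1.02±0.21) and Klf4 (0.44±0.14), and 4 fell, with Dppa3 (-1.86±0.33), Tbx3 (-1.11±0.18) and Tfcp2l1 (-0.96±0.18). With TMM scaling 9 rose and 3 fell (camera adjusted p = 0.0877, adjusted p = 0.766 with an estimated correlation). Dnmt3a fell (-0.92±0.18), Dnmt3l rose (0.58±0.20) and Dnmt3b did not pass (0.30±0.18) but rose with TMM scaling (0.47, adjusted p = 0.00884). Dnmt3l lost its call with the ESC line as block (0.44, adjusted p = 0.08) and without the J-34 S/L (0.38) or J-34 PKCi/L library (0.39). Klf4 lost it without the same 2 libraries (0.36 and 0.34). Of 12 p53 targets 9 fell (camera adjusted p = 0.0102, adjusted p = 0.557 with an estimated correlation), with Perp (-2.03±0.24) and Trp53inp1 (-1.06±0.17), and the imprinted Slc38a4 fell (-2.83±0.20). Large moves included rises of Ifi27l1 (6.02±0.25), A2m (5.38±0.18), the interferon-induced Irgm1 (3.57±0.27) and Ndufa4l2 (3.51±0.24) and falls of Htra1 (-4.43±0.19), Wnt7b (-3.59±0.28) and Calml4 (-3.52±0.25). In limma 750 genes rose and 3046 fell (19.8% higher) around a median shift of -0.17, and with TMM scaling 2194 rose and 2534 fell (46.4% higher). Without the J-34 S/L library 443 genes rose and 2122 fell, and without the J-34 PKCi/L library 453 and 2424. Counts adjusted over the list alone were the same except 2 higher and 6 lower for ERK pathway target and feedback genes and 2 higher and 3 lower for Wnt and beta-catenin target genes. The same adjustment gave 0 higher and 12 lower for primitive endoderm markers and 1 higher and 11 lower for actin, SRF and YAP target genes.

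After 3 passages back in S/L, returned from 2i/L, ERK feedback genes had risen again compared with 2i/L at passage 20, and Wnt targets and Hox genes had fallen. Spry4 rose from 0.873±0.0208 to 56.1±11.0 CPM and Dusp6 from 3.05±0.562 to 60.2±11.2 CPM (mean ± SD, n = 3 libraries each, 5.35±0.18, adjusted p = 4.15e-23 and 4.09±0.16, adjusted p = 1.54e-21). Of 19 ERK pathway genes 17 rose and 1 fell (camera adjusted p = 1.19e-13, adjusted p = 0.0427 with an estimated correlation), Dusp4 by 3.88±0.16. Of 14 actin, SRF and YAP targets 12 rose (camera adjusted p = 9.3e-11, adjusted p = 0.0427 with an estimated correlation). Among them were Tagln (3.23±0.17) and Cnn2 (2.93±0.16). All 9 Hox genes fell (camera adjusted p = 8.96e-06, adjusted p = 0.0427 with an estimated correlation), with Hoxa10 (-3.32±0.22) and Hoxd9 (-2.31±0.20). In turn 10 of 11 Wnt targets fell (camera adjusted p = 0.00144, adjusted p = 0.254 with an estimated correlation), Cdx1 by -4.89±0.16. Lin28a (5.05±0.20), Dnmt3l (4.27±0.17), Dnmt3a (1.56±0.15) and Dnmt3b (1.38±0.15) rose, and Nanog (-2.37±0.12), Tfcp2l1 (-3.22±0.14), Prdm14 (-1.92±0.15) and Dazl (-3.76±0.19) fell. Naive factors fell in 9 of 15 cases (camera adjusted p = 0.00134, adjusted p = 0.308 with an estimated correlation). Fibroblast markers fell in 10 of 17 (camera adjusted p = 0.001, adjusted p = 0.322 with an estimated correlation). Among them were Col3a1 (-5.62±0.21) and Col1a1 (-3.86±0.17). Glycolysis genes rose in 10 of 15 cases (camera adjusted p = 1.06e-06, adjusted p = 0.291 with an estimated correlation), with Pdk1 (2.35±0.13) and Slc2a1 (1.91±0.15). Peg10 (5.25±0.13), Enpp3 (5.08±0.18), Plagl1 (-4.46±0.18), Aqp3 (-4.64±0.19) and Cdkn1a (-2.12±0.15) were further large moves. In limma 2047 genes rose and 3922 fell (34.3% higher), around a median shift of -0.11. With TMM scaling the numbers were 3596 and 3529 (50.5% higher). These list counts adjusted over the list alone were the same except 1 higher and 10 lower for naive pluripotency factors, 13 higher and 0 lower for actin, SRF and YAP target genes and 11 higher and 1 lower for glycolysis genes.

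In the returned ESCs cholesterol synthesis, glycolysis and ERK pathway genes lay above the level of ESCs kept in S/L to passage 20. Some of these genes were themselves lower in S/L at passage 20 than at passage 10. Cholesterol synthesis genes, Spry4 (-1.79), Dusp6 (-0.86) and Axin2 (-1.48) fell there, across the 2 library sets and a median shift of -0.52. With TMM scaling Spry4 (-1.23) and Axin2 (-1.01) fell and Dusp6 did not pass (-0.29). A lasting effect of 2i/L therefore cannot be told from a lower level in the S/L libraries of passage 20. Sc4mol rose from 12.5±0.719 to 95.5±25.2 CPM (mean ± SD, n = 3 libraries each, 2.86±0.13, adjusted p = 3.33e-18). All 16 cholesterol synthesis genes rose (camera adjusted p = 1.64e-22, adjusted p = 0.145 with an estimated correlation). Among them were Mvd (2.77±0.13) and Insig1 (2.72±0.14). All 15 glycolysis genes rose (camera adjusted p = 7.95e-10, adjusted p = 0.344 with an estimated correlation). Among them were the glucose transporter gene Slc2a1 (2.35±0.15), Slc16a3 (2.37±0.19) and Hk2 (1.80±0.14). Of 19 ERK pathway genes 14 rose and none fell (camera adjusted p = 0.00285, adjusted p = 0.489 with an estimated correlation), with Ier3 (2.32±0.19), Dusp4 (1.27±0.16), Spry4 (1.20±0.18) and Dusp6 (0.74±0.16). Of 11 Wnt targets 9 rose (camera adjusted p = 0.00695, adjusted p = 0.351 with an estimated correlation), Axin2 by 1.23±0.16. Naive factors fell in 6 of 15 cases and rose in 2 (camera adjusted p = 1.37e-05, adjusted p = 0.344 with an estimated correlation), against 12 and 2 with TMM scaling. Tbx3 (-1.54±0.15), Tfcp2l1 (-0.96±0.14) and Klf4 (-0.44±0.12) fell and Gbx2 rose (1.99±0.19). Nanog (-0.71±0.12) and Dazl (-0.76±0.19) fell below S/L, and Pou5f1 (-0.01±0.14), Sox2 (-0.25±0.12) and Esrrb (-0.25±0.13) did not pass. With TMM scaling all of these fell, Pou5f1 (-0.26, adjusted p = 0.0298), Sox2 (-0.50, adjusted p = 6.03e-06) and Esrrb (-0.50, adjusted p = 1.43e-05). Without the J-35 S/L library Sox2 (-0.33) and Esrrb (-0.36) fell too, as did Esrrb without the J-34 returned library (-0.37).

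Imprinted genes differed from S/L in both directions. The paternally expressed Peg10 (3.16±0.13), Sgce (2.3±0.19) and Mest (1.62±0.16) were among 10 of 22 that rose (camera adjusted p = 0.17, adjusted p = 0.543 with an estimated correlation). The maternally expressed H19 rose (2.60±0.23) and Grb10 fell (-2.14±0.23). Their list of 16 held 4 higher and 2 lower, or 3 and 6 with TMM scaling (camera adjusted p = 0.605, adjusted p = 0.804 with an estimated correlation). Dnmt3l (1.09±0.17) and Dnmt3a (1.06±0.15) rose above S/L and Dnmt3b did not pass (0.03±0.15). Methylation machinery genes rose in 7 of 12 cases (camera adjusted p = 0.181, adjusted p = 0.691 with an estimated correlation). Primitive endoderm markers rose in 6 of 13 cases (camera adjusted p = 0.0267, adjusted p = 0.489 with an estimated correlation). Among them were Cubn (2.18±0.23), Col4a1 (2.05±0.17) and Col4a2 (1.92±0.18). The formative marker Tcf15 rose (1.87±0.17), and 3 of 12 p53 targets fell, Sesn2 by -1.17±0.17 (camera adjusted p = 0.00442, adjusted p = 0.489 with an estimated correlation). Bhlhe40 (3.24±0.16), Egln3 (3.13±0.17) and Adm (2.96±0.19) were among the largest rises, and Trim66 (-2.69±0.21), Hrk (-2.65±0.22), Usp26 (-2.44±0.21), Ephx2 (-2.34±0.20) and Mcf2 (-2.33±0.17) the largest falls. In limma 4230 genes rose and 858 fell (83.1% higher), around a median shift of 0.20. With TMM scaling 2754 rose and 3009 fell (47.8% higher), and the comparison spans passage 20 to passage 23. Without the J-37 returned library 4465 genes rose and 562 fell. Called members adjusted over the list alone were the same except 11 higher and 0 lower for Wnt and beta-catenin target genes and 6 higher and 3 lower for maternally expressed imprinted genes. The same adjustment gave 10 higher and 2 lower for paternally expressed imprinted genes and 0 higher and 1 lower for p53 target genes.

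**Figure D3:**
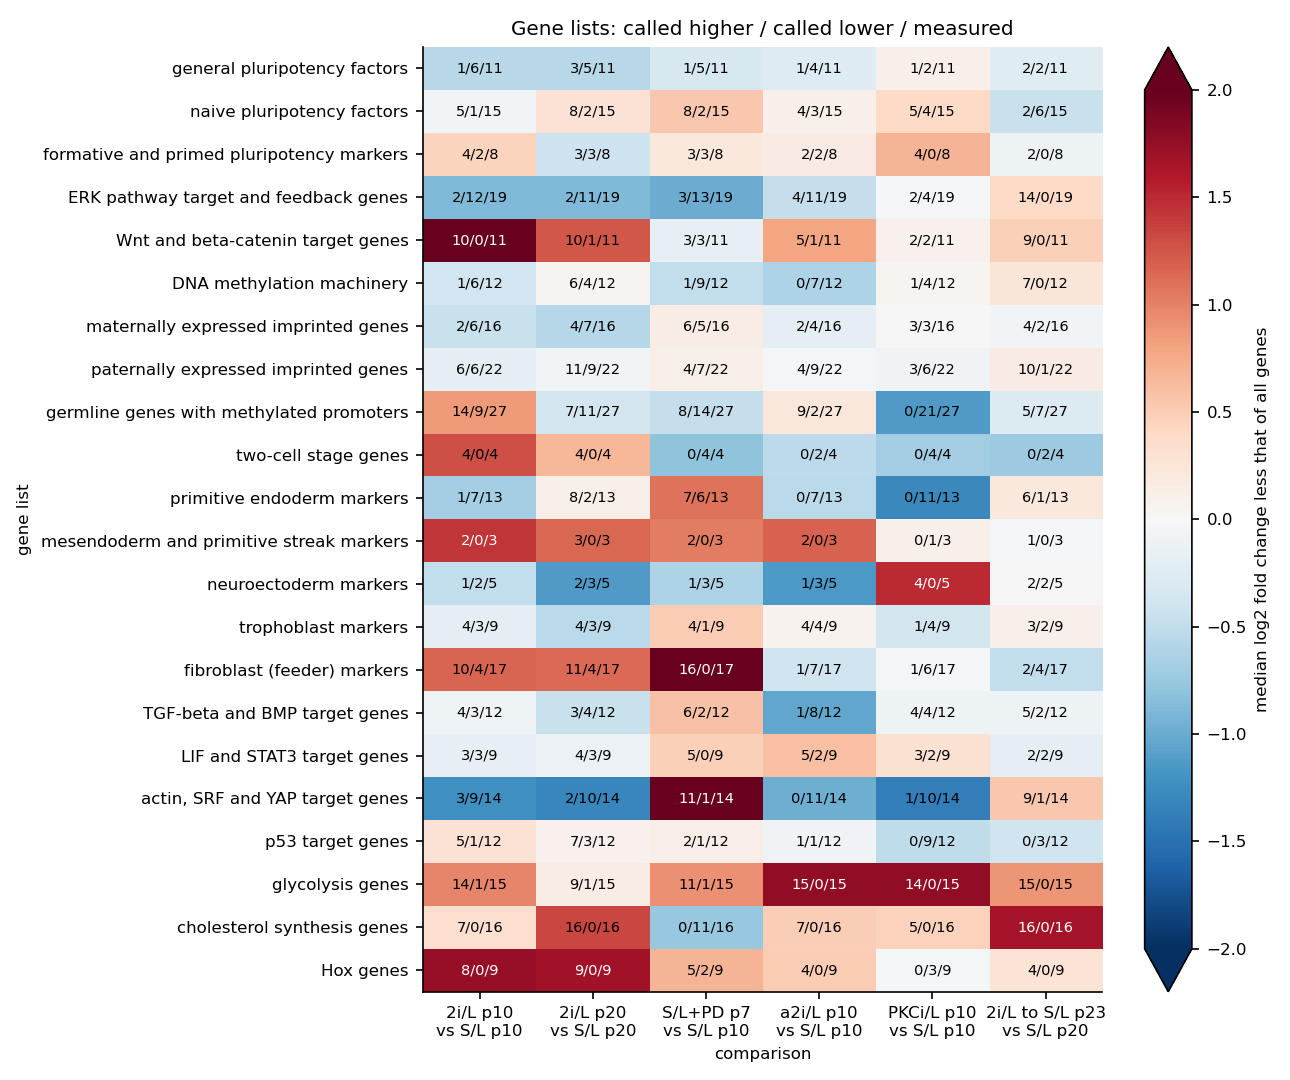
Median log2 fold change of the 22 gene lists in the 6 main comparisons, less that of all genes. The numbers are the genes called higher, called lower and measured in each list.

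Set directly against 2i/L at passage 10 (n = 2 libraries per group), a2i/L held more ERK feedback transcripts and fewer Hox, Wnt target and two-cell stage transcripts. Spry4 rose from 0.155±0.0636 to 26.4±9.27 CPM (mean ± SD, 5.32±0.22, adjusted p = 1.55e-19). Of 19 ERK pathway genes 9 rose and 3 fell (camera adjusted p = 0.000226, adjusted p = 0.429 with an estimated correlation). Among them were Egr1 (2.92±0.24) and Dusp6 (2.56±0.19). Of 11 Wnt targets 6 fell (camera adjusted p = 0.00433, adjusted p = 0.429 with an estimated correlation), with Sp5 (-3.47±0.23) and Notum (-3.17±0.29). Of 9 Hox genes 7 fell (camera adjusted p = 0.00471, adjusted p = 0.39 with an estimated correlation), with Hoxa10 (-3.30±0.27). All 4 two-cell stage genes fell, Zscan4d by -2.46±0.26 (camera adjusted p = 0.00065, adjusted p = 0.39 with an estimated correlation). Lin28a (4.70±0.25), Dnmt3l (2.72±0.20) and Hpn (4.08±0.26) rose, and Dppa3 (-2.97±0.33), Prdm14 (-1.17±0.18), Dazl (-3.23±0.23), Lefty1 (-3.88±0.34), Lefty2 (-3.85±0.25), Aspa (-4.96±0.25), Col3a1 (-4.75±0.26) and Meis2 (-4.70±0.29) fell. In limma 1523 genes rose and 3095 fell (33.0% higher, median shift -0.12), or 2772 and 2929 with TMM scaling (48.6% higher), and without the J-34 2i/L library 3065 genes passed (982 higher, 2083 lower) in place of 4618. Counts adjusted over the list alone were the same except 10 higher and 3 lower for ERK pathway target and feedback genes.

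In PKCi/L against 2i/L at passage 10 (n = 2 libraries per group), ERK feedback and neuroectoderm genes rose and Hox and germline genes fell. Dusp6 rose from 3.2±0.141 to 56.0±2.82 CPM (mean ± SD, 3.93±0.19, adjusted p = 1.33e-18). Of 19 ERK pathway genes 11 rose and 2 fell (camera adjusted p = 9.12e-07, adjusted p = 0.157 with an estimated correlation), Spry4 by 6.57±0.22. All 5 neuroectoderm markers rose (camera adjusted p = 8.46e-06, adjusted p = 0.0482 with an estimated correlation), with Sox11 (2.71±0.24) and Pax6 (2.48±0.26). Of 9 Hox genes 8 fell (camera adjusted p = 1.22e-05, adjusted p = 0.0482 with an estimated correlation), with Hoxa10 (-3.81±0.27). Germline genes fell in 18 of 27 cases (camera adjusted p = 1.29e-06, adjusted p = 0.198 with an estimated correlation), with Dazl (-5.73±0.23) and Fkbp6 (-5.43±0.28). Wnt targets fell in 9 of 11 (camera adjusted p = 0.000218, adjusted p = 0.157 with an estimated correlation), with Sp5 (-4.86±0.23) and Cdx1 (-4.68±0.20). Dnmt3l (5.24±0.20), Dnmt3b (2.45±0.18), Trh (6.42±0.32) and Crmp1 (5.70±0.23) rose, and Dppa3 (-4.93±0.33), Aurkc (-5.72±0.23) and Calcoco2 (-5.70±0.22) fell. In limma 1494 genes rose and 4300 fell (25.8% higher, median shift -0.19), or 3445 and 3491 with TMM scaling (49.7% higher). List counts adjusted over the list alone were the same except 11 higher and 3 lower for ERK pathway target and feedback genes and 2 higher and 19 lower for germline genes with methylated promoters.

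In S/L+PD at passage 7 against 2i/L at passage 10 (n = 2 libraries per group), ERK pathway genes split evenly, 6 higher and 6 lower of 19 (camera adjusted p = 0.327, adjusted p = 0.817 with an estimated correlation). Wnt targets, cholesterol synthesis genes and fibroblast markers set the media apart. Of 11 Wnt targets 9 fell and none rose (camera adjusted p = 2.3e-09, adjusted p = 0.0143 with an estimated correlation). Cdx1 fell from 33.1±2.98 to 0.060±0.0849 CPM (mean ± SD, -5.91±0.20, adjusted p = 2.62e-23), with Sp5 (-5.29±0.23) and Axin2 (-4.29±0.20). All 16 cholesterol synthesis genes fell (camera adjusted p = 5.13e-11, adjusted p = 0.132 with an estimated correlation). Among them was Dhcr7 (-2.21±0.18). Fibroblast markers rose in 16 of 17 cases (camera adjusted p = 6.21e-28, adjusted p = 0.0143 with an estimated correlation), Col5a2 by 5.23±0.23. With them actin, SRF and YAP targets rose in 13 of 14 cases (camera adjusted p = 5.06e-26, adjusted p = 0.00271 with an estimated correlation). Among them were Thbs1 (9.23±0.24), Acta2 (7.41±0.22) and Tagln (6.75±0.21). Of 9 Hox genes 6 fell (camera adjusted p = 0.000796, adjusted p = 0.0853 with an estimated correlation). Among them was Hoxa10 (-2.03±0.27). Dnmt3l (4.47±0.20) and Fos (5.91±0.27) rose, and Dazl (-2.02±0.23), Stra8 (-3.28±0.23) and Ntn1 (-4.43±0.25) fell. In limma 1647 genes rose and 2630 fell (38.5% higher), or 2626 and 2562 with TMM scaling (50.6% higher), and without the J-34 2i/L library 2829 genes passed (1140 higher, 1689 lower) in place of 4277. Without the J-35 2i/L library 1700 fell, and without the J-37 S/L+PD library 1670. Called numbers adjusted over the list alone were the same except 7 higher and 7 lower for ERK pathway target and feedback genes and 0 higher and 7 lower for Hox genes.

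Between passage 10 and passage 20 in S/L, cholesterol synthesis genes fell and fibroblast markers and some formative genes rose, in a comparison where passage and library set coincide (n = 2 and n = 3 libraries). Sc4mol fell from 58.4±5.37 to 12.5±0.719 CPM (mean ± SD, -2.18±0.15, adjusted p = 4.25e-14). All 16 cholesterol synthesis genes fell, or 13 with TMM scaling (camera adjusted p = 2.54e-07, adjusted p = 0.487 with an estimated correlation). Otx2 (2.52±0.23) and Zic2 (1.86±0.17) rose, 4 of 8 formative and primed markers in all (camera adjusted p = 3.56e-05, adjusted p = 0.251 with an estimated correlation). Fibroblast markers rose in 13 of 17 cases (camera adjusted p = 7.98e-14, adjusted p = 0.251 with an estimated correlation). Among them were Col3a1 (2.41±0.24) and Dcn (2.36±0.25). Lars2 (8.14±0.68), Hist1h2ba (5.09±0.29) and Hist1h2aa (4.93±0.26) had the largest rises. That of Lars2, a feature treated as resembling ribosomal RNA, is not read as induction of the gene. Tgm2 (-4.68±0.24) and the small RNA genes U3 (-4.01±0.23) and SCARNA6 (-3.55±0.21) had the largest falls. In limma 890 genes rose and 7806 fell (10.2% higher) around a median shift of -0.52, but 3465 rose and 3428 fell with TMM scaling (50.3% higher), and 124 genes passed in opposite directions.

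Between passage 10 and passage 20 in 2i/L, glycolysis and germline genes fell and fibroblast markers rose, again with passage and library set coinciding (n = 2 and n = 3 libraries). Sohlh2, a regulator of germ cell development, fell from 66.9±3.75 to 10.9±0.402 CPM (mean ± SD, -2.57±0.18, adjusted p = 6.22e-14). Of 27 germline genes 19 fell (camera adjusted p = 0.000294, adjusted p = 0.573 with an estimated correlation), Dazl by -1.54±0.21. Of 15 glycolysis genes 13 fell (camera adjusted p = 0.00019, adjusted p = 0.573 with an estimated correlation), with Pgk1 (-1.94±0.16) and Pfkl (-1.93±0.17). Of 17 fibroblast markers 15 rose (camera adjusted p = 1.94e-16, adjusted p = 0.176 with an estimated correlation), with Postn (2.83±0.26) and Col1a1 (2.45±0.19). Dnmt3l (2.02±0.19) and Dnmt3b (1.45±0.16) rose, as did Adam23 (3.16±0.18), Col12a1 (3.05±0.23) and the ribosomal RNA-like feature Lars2 (7.70±0.68). Ephx2 (-5.06±0.22), SCARNA6 (-4.07±0.21) and SCARNA1 (-3.92±0.22) fell. In limma 1760 genes rose and 4811 fell (26.8% higher) around a median shift of -0.22, against 3305 and 3413 with TMM scaling (49.2% higher). Without the J-34 library of passage 10, 1164 rose. In both passage comparisons the numbers adjusted over the list alone were the same except 1 higher and 22 lower for germline genes with methylated promoters.

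The genes changed in 2i/L at passage 20 were then read in the passage 10 comparisons, which share no library with them. The 6469 genes that were higher at passage 20 had a median log2 fold change of 0.26 in 2i/L at passage 10, against 0.04 for all genes. Of these 36.9% rose there, against 22.7% of all genes (camera adjusted p = 1.62e-19, adjusted p = 0.436 with an estimated correlation). The 1592 genes that were lower had a median of -0.51, and 51.4% of them fell, against 17.5% of all genes (camera adjusted p = 1.02e-26, adjusted p = 0.436 with an estimated correlation). In S/L+PD the medians of the higher and lower genes were 0.03 and -0.28 against -0.06 for all genes (camera adjusted p = 0.000219 and 5.78e-05, adjusted p = 0.653 for both with an estimated correlation). In a2i/L they were -0.01 and -0.29 against -0.09 (camera adjusted p = 0.00021 and 2.18e-06, adjusted p = 0.653 for both with an estimated correlation). In PKCi/L the higher genes lay below all genes, at -0.21 against -0.17 (camera adjusted p = 0.0472, adjusted p = 0.808 with an estimated correlation). The lower genes lay at -0.13 (camera adjusted p = 0.22).

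Genes of chromosomes 6 and 8 were higher as 2 blocks in each of the 3 ESC lines at 2i/L passage 20, and stayed higher after the return to S/L. The planned scale was the median log2 deviation from all 19 libraries for genes with a mean of at least 10 CPM. On it chromosome 8 had a mean level of 0.24 in 2i/L and 0.17 after the return, against -0.52 in S/L at passage 20 (n = 3 libraries each). Chromosome 6 had 0.21, 0.12 and -0.56. These levels carry the shift of all genes between libraries, so a level relative to the genes on all other chromosomes was added after the files were seen. Relative to S/L at passage 20, chromosome 8 then stood at 0.48±0.02 in 2i/L (mean ± SD of 3 libraries, 0.46 to 0.50), a 1.40-fold level, and chromosome 6 at 0.47±0.08 (0.42 to 0.56), a 1.39-fold level. After the return chromosome 8 stood at 0.53±0.03 (1.44-fold) and chromosome 6 at 0.51±0.03 (1.42-fold), and the 368 values of other chromosomes and libraries averaged -0.01±0.06 (-0.22 to 0.24). Of 359 chromosome 8 genes 86.9% lay above the median of the others in 2i/L (camera adjusted p = 1.47e-11, adjusted p = 0.997 with an estimated correlation, and 0.0136 with TMM scaling besides). Of 292 chromosome 6 genes the share was 83.9% (camera adjusted p = 1.75e-09, adjusted p = 0.997 with an estimated correlation, and 0.111 with TMM scaling besides). After the return the shares were 92.2% and 91.1% (camera adjusted p = 1.05e-27 and 7.13e-22, adjusted p = 0.987 for both with an estimated correlation, and adjusted p = 0.000507 and 0.00928 with TMM scaling and an estimated correlation). Chromosome 13 lay lower in 2i/L at passage 20, by -0.22, -0.21 and -0.22 in the 3 lines (camera adjusted p = 0.00038, adjusted p = 0.997 with an estimated correlation), and by -0.06 to -0.15 after the return (camera adjusted p = 0.0752). It also differed in the interaction (-0.22, camera adjusted p = 9.63e-07, adjusted p = 0.993 with an estimated correlation) and lay higher in PKCi/L against S/L (0.15, camera adjusted p = 0.015, adjusted p = 0.989 with an estimated correlation). The histone genes Hist1h2aa and Hist1h2ba lie on chromosome 13. A histone list chosen after the results were seen had medians of -0.92, -1.10 and 0.60 in 2i/L at passage 20, the interaction and PKCi/L. The part of histone genes in the chromosome 13 level was not tested. Chromosome 19 was raised in line J-34, by 0.24 in 2i/L and 0.13 after the return. Of genes named above, Nanog, Dppa3, Hk2, Peg10, Sgce, Mest, Bhlhe40, Hoxa10, A2m, Col1a2, Trh, Stra8, Tuba3a and Tuba3b lie on chromosome 6. Klf2, Dusp4, Mvd, Col4a1, Col4a2 and Dpep3 lie on chromosome 8. The named genes Sc4mol, Ctgf, Cyr61, Ifi27l1, U3, SCARNA1 and SCARNA6 were not placed, so they may lie on any chromosome.

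**Figure D4:**
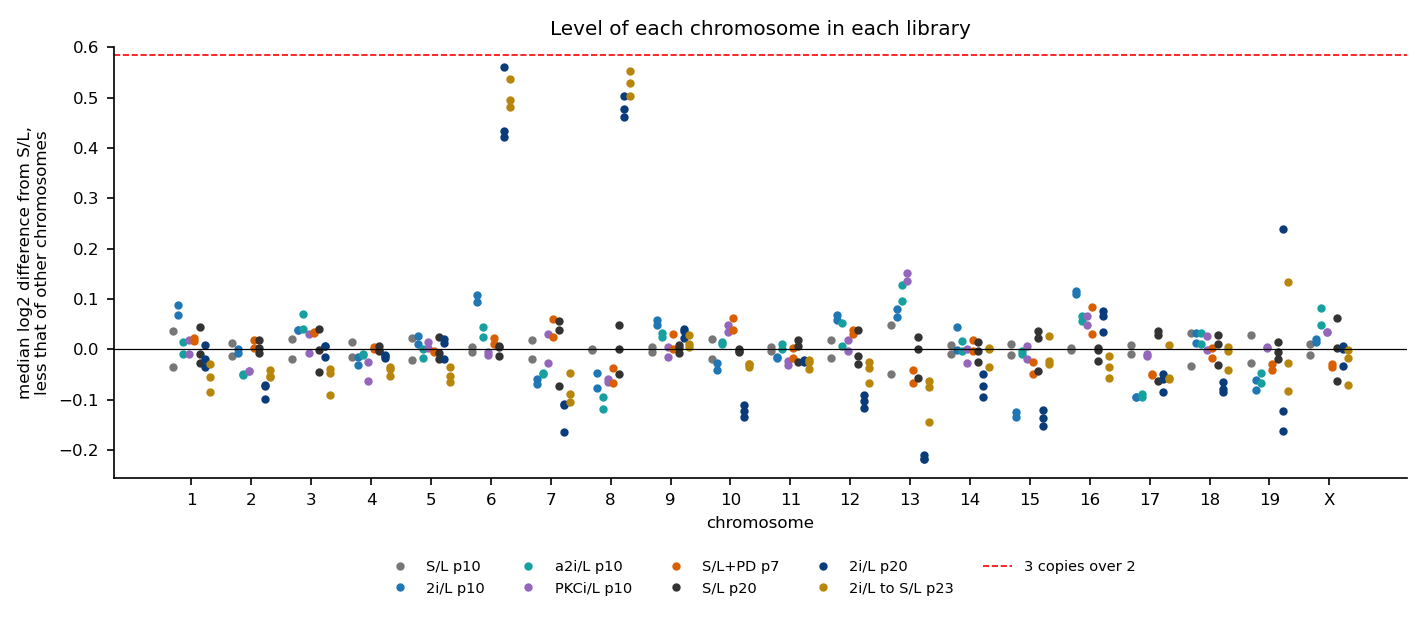
Median level of the genes of each chromosome in each library, relative to the control libraries and to the genes on all other chromosomes. The dashed line marks 3 copies over 2.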

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

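The tests of explanations in this part were chosen after the results were seen, except the regrouping of libraries, which was planned. What drew attention was a difference between passages in the effect of 2i/L, a set of raised chromosomes in 3 ESC lines, markers of another cell type, and 2 sets of libraries that stood apart.

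The effect of 2i/L against S/L differed between passage 20 and passage 10 for 4792 genes in limma's interaction test. The differences in log2 fold change were 4.55 for Inhbb, 4.17 for Adam23 and 4.16 for Cntn2, and -4.78 for Hist1h2aa, -4.76 for Lef1 and -4.22 for Igfbp4. Cholesterol synthesis genes differed by 2.45 (Mvd) and 2.48 (Sc4mol), and germline genes by -2.87 (Sohlh2) and -2.80 (Tuba3b). Glycolysis genes differed by -1.59 (Pgk1) and -1.41 (Ldha) and the basement membrane genes Col4a1 and Col4a2 by 3.48 and 2.70. Of these Mvd, Col4a1 and Col4a2 lie on chromosome 8 and Tuba3b on chromosome 6, and Sc4mol was not placed on a chromosome.

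Genes of chromosomes 6 and 8 were raised in all 3 lines at 2i/L passage 20 and after the return. A batch effect of the later libraries would also raise them in S/L at passage 20 against passage 10, but the chromosome 8 median there was 0.013. A response that follows the medium would fall on the return to S/L, but chromosome 8 stood 0.035 above 2i/L. With extra copies of whole chromosomes every stretch would be raised, and the lowest of 20 medians of gene blocks along the 2 chromosomes was 0.335. Extra copies of both chromosomes in most cells are therefore a likely hypothesis, with 3 copies in every cell giving 0.585, and a karyotype or DNA reads would test it.

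Fibroblast markers rose with S/L+PD and in part with 2i/L. Feeder cells carried into the S/L+PD libraries would raise most of them, although the labels' sort for SSEA1 should remove such cells. The rise of 16 of 17 is the pattern to be explained, so it adds no support for feeder cells. The same carry-over in 2i/L at passage 20, with feeder cells in the same state, would bring the ratio of Tagln to Col1a1 of S/L+PD. That ratio was 0.190 and 0.166 in the S/L+PD libraries, and at most 0.0107 in 2i/L at passage 20. For S/L+PD feeder cells remain a candidate explanation that was not tested, and expression by the ESCs themselves was not excluded. Feeder cells in the same state do not account for the collagen genes of 2i/L. But the ratio differed between media, with 0.0039 and 0.0043 in 2i/L and 2.2275 and 2.4943 in S/L at passage 10. Feeder cells kept in 2i/L need not hold the S/L+PD ratio, so the ratio cannot decide on feeder cells in 2i/L.

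The libraries of passages 20 and 23 differed from those of passages 7 and 10 in level and in features that resemble ribosomal RNA. These were summed over Lars2, Mir5105, Mir5102, AY036118 and mmu-mir-689-2, with Lars2 the highest feature of every later library. Whether their reads came from ribosomal RNA was not tested. The lowest sum of the later set was 3.8 times the highest of the earlier set. A change in library preparation might give this, but every later library is also of a later passage. The comparisons of passage 20 with passage 10 within a medium cannot part a batch from passage. In the interaction a batch effect equal in both media would cancel on the log scale, but an unequal one cannot be told from passage.

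In the planned regrouping the 6 libraries of each comparison with 3 per group were split in all 10 ways, and in each of the 3 comparisons only 1 of 10 splits, the real one, called as many genes. With limma the other 9 splits called 0 genes, and at unadjusted p under 0.05 at most 1386 genes (2i/L against S/L at passage 20), 2497 (return against S/L) and 1033 (return against 2i/L). Each of these splits puts the real difference into the spread within its groups, so the 0 calls do not measure false calls. With 10 splits the share cannot go under 0.05.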

How the results depend on the processing

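The restriction to genes with a mean of at least 5 CPM, the runs without chromosomes 6 and 8, the levels less the median of all genes, and the estimated correlation for gene sets were chosen after the results were seen, the other alternatives before. No called gene named in the text turned its direction, but with TMM scaling 124 of all genes passed in opposite directions in S/L between passages 10 and 20. Total counts of called genes stayed within 1.5 times their value with TMM scaling, pseudocounts of 0.1 and 1 CPM, the replicate block and the runs without chromosomes 6 and 8 (7040 genes in 2i/L and 4079 after the return against S/L at passage 20). The split into higher and lower genes moved further with TMM scaling, as in PKCi/L against S/L, from 750 and 3046 to 2194 and 2534. Dropping the filter changed nothing, since the filter removed no gene. Leaving out 1 library gave, with fewer libraries in the test, 3809 to 4081 called genes in 2i/L at passage 10, 7113 to 7857 at passage 20, 3279 to 3591 in S/L+PD, 2281 to 2537 in a2i/L, 2565 to 2941 in PKCi/L, and 3993 to 5027 and 5110 to 5530 for the return against S/L and against 2i/L. Against 2i/L the ranges were 3065 to 3404 (a2i/L), 4469 to 5147 (PKCi/L) and 2829 to 3427 (S/L+PD), between passages 7307 to 8695 (S/L) and 4573 to 6431 (2i/L), and 3639 to 4918 for the interaction. With only genes of at least 5 CPM, so fewer genes tested, 3232 genes passed in 2i/L at passage 10, 2932 in S/L+PD, 2295 in a2i/L, 2333 in PKCi/L and 3851 for the return against 2i/L, and 2799 (a2i/L), 3687 (PKCi/L) and 2647 (S/L+PD) against 2i/L and 3161 for the interaction.

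The replicate block, with ESC lines from the titles, gave 5232, 8084, 4476, 3672, 3737 and 5128 called genes in the 6 main comparisons in the order of the report's methods, ended the call of Dnmt3l in PKCi/L against S/L (0.444) and of no other named gene. Of 387 values of named genes 370 kept their call with TMM scaling, 16 gained and 1 lost it, and of 1885 leave-one-out values 14 lost and 6 gained it. Of 286 list tests 124 lost their call with an estimated correlation and 25 with TMM scaling, which added 1. The gene that lost it with TMM scaling was Dnmt1 in 2i/L at passage 20 (0.154). The estimated correlation of the passage 20 genes called higher and lower was 0.288 and 0.307 without scaling. For the sets called with TMM scaling it was 0.033 and 0.029. With both choices the 2 sets kept their call in 2i/L at passage 10 (camera adjusted p = 0.000652). Losses with an estimated correlation alone thus went with the unscaled shift between libraries, and other causes were not tested. Relative medians of the passage 20 genes changed as follows, by camera p not adjusted over sets. With an estimated correlation the higher genes lost their call in 2i/L (0.219), S/L+PD (0.088), a2i/L (0.075) and PKCi/L (-0.047), and the lower genes in 2i/L (-0.542), S/L+PD (-0.216) and a2i/L (-0.209). In PKCi/L the lower genes gained a call with TMM scaling (0.064), and the higher genes lost it with the replicate block (-0.043) and with TMM scaling and an estimated correlation together (-0.076). After adjustment over the 8 sets, that last choice also took the S/L+PD sets (adjusted p = 0.0574 for both) and the a2i/L sets (adjusted p = 0.0604 and 0.0574) above 0.05. Chromosome levels carry the shift of all genes, which both alternatives remove by construction. With TMM scaling chromosome 6 stood at -0.131 in S/L at passage 20 and 0.287 after the return and chromosome 8 at -0.089 and 0.339. Less the median of all genes chromosome 6 stood at -0.249 and 0.217 and chromosome 8 at -0.213 in S/L. A limit of 1 CPM changed no level by much. Values are rounded to 0.01 CPM, and an effect of depth on genes with low CPM was not tested.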

Other observations

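The gene lists and both hypotheses in this part were chosen after the results were seen, and their camera p values are adjusted over the 5 lists of a comparison.

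Hypoxia-response genes rose in every medium against S/L. In a2i/L 17 of 19 rose (median log2 fold change 2.22, n = 2 libraries per group, camera adjusted p = 1.61e-34, adjusted p = 0.00237 with an estimated correlation), Ndrg1 by 4.37±0.21. In S/L+PD 18 rose (1.30, adjusted p = 1.79e-15, adjusted p = 0.041 with an estimated correlation), and in 2i/L at passage 10 15 rose (1.46, adjusted p = 1.31e-11, adjusted p = 0.0925 with an estimated correlation). In PKCi/L 15 rose, with 1 lower (1.32, adjusted p = 1.39e-22, adjusted p = 0.0064 with an estimated correlation). At passage 20 16 rose in 2i/L (0.82, adjusted p = 0.00119, adjusted p = 0.367 with an estimated correlation), or 12 with TMM scaling (median 0.44). After the return 17 rose (1.42, adjusted p = 5.33e-15, adjusted p = 0.0496 with an estimated correlation), Egln3 by 3.13±0.17. With TMM scaling 15 rose and 1 fell (1.18). The 4 passage 10 and 7 comparisons share their S/L libraries, so they are not independent of one another. Against 2i/L at passage 10 the median was 0.79 in a2i/L (12 higher, 1 lower). It was -0.11 in S/L+PD (2 and 2) and -0.37 in PKCi/L (5 and 10, or 6 and 5 with TMM scaling). A response shared by the media therefore cannot be told from a low level in the S/L libraries.

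Replication-dependent histone genes fell in 50 of 57 cases in 2i/L against S/L at passage 20, or 56 with TMM scaling (medians -0.92 and -1.30, n = 3 libraries per group, camera adjusted p = 3.97e-31, adjusted p = 0.245 with an estimated correlation). In S/L, 36 rose and 4 fell from passage 10 to passage 20, or 53 and 0 with TMM scaling (0.59 and 1.16, adjusted p = 7.95e-33, adjusted p = 0.11 with an estimated correlation). Against S/L at passage 10 they rose in PKCi/L in 35 cases, or 53 with TMM scaling (0.60 and 0.77, adjusted p = 2.04e-23, adjusted p = 0.14 with an estimated correlation). In a2i/L 26 rose and 0 fell (0.47, camera adjusted p = 1.07e-11, adjusted p = 0.457 with an estimated correlation). In S/L+PD 1 rose and 28 fell (-0.50, camera adjusted p = 1.53e-05, adjusted p = 0.761 with an estimated correlation). In 2i/L 14 rose and 3 fell (0.21, camera adjusted p = 0.323). Amino-acid and ATF4 response genes fell in 15 of 19 cases after the return against S/L at passage 20, or in 19 with TMM scaling (-0.87 and -1.11, adjusted p = 4.97e-18, adjusted p = 0.07 with an estimated correlation).

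Interferon-response genes rose in all 12 cases in PKCi/L against S/L (2.12, n = 2 libraries per group, camera adjusted p = 2.04e-23, adjusted p = 0.00182 with an estimated correlation). A hypothesis was that the S/L libraries of passage 10 were low, which would bring the median against 2i/L under 0.5. It was 1.756 there, with 12 of 12 higher (adjusted p = 3.72e-12, adjusted p = 0.0207 with an estimated correlation), which argues against that explanation. In S/L 10 of 12 rose from passage 10 to passage 20, or 11 with TMM scaling (0.80 and 1.20, adjusted p = 3.93e-12, adjusted p = 0.0227 with an estimated correlation).

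A second hypothesis was that genes changed in 2i/L at passage 10 stay changed after the return to S/L. The 2941 genes that were higher lay 0.019 above all genes in the return against S/L at passage 20 (camera adjusted p = 0.842), and the 2268 that were lower lay 0.032 above (camera adjusted p = 0.842), which argues against a general carry-over. In 2i/L at passage 20 the same sets lay at 0.52 and -0.45 relative to all genes (camera adjusted p = 1.62e-23 and 2.62e-24, adjusted p = 0.147 for both with an estimated correlation).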
